A study of Homo sapiens with 22 samples.

How the data were processed

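RNA of haematopoietic progenitor cells derived from H1 embryonic stem cells was measured by sequencing of polyA-selected RNA in 22 libraries, 12 without doxycycline (UT) and 10 with doxycycline (DOX), which switches on ectopic MYC. Per the submitters' processing notes, reads were processed with Trim Galore 0.6.5, STAR and Salmon against hg38; versions of STAR and Salmon, the annotation release, the strand setting, any filters and the day on which doxycycline was added were not given in the sources used here. The deposited values are expected counts per gene and library (estimated reads, not normalised), of which 88.3% were whole numbers, and all 22 columns were used. They were rounded to whole numbers. Of 60240 genes, 23698 had 0 counts everywhere. Gene positions came from GENCODE 29 on GRCh38, which matched 58020 of the gene identifiers and may differ from the annotation behind the counts.

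Groups were the 11 combinations of arm and day in the labels, with 2 libraries each. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10), which left 20115, and libraries were scaled by TMM. A single quasi-likelihood fit with 1 coefficient per group (11 residual degrees of freedom, common biological coefficient of variation 0.184) gave every comparison, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were DOX against UT averaged over days 12 to 20 and on each day, UT day 20 and DOX day 20 against UT day 10, the change of the DOX against UT difference from day 12 to day 20, and F tests of any difference between days within each arm. CPM values are TMM-scaled. Positions on the line from UT day 10 to UT day 18 used log2 CPM with a prior count of 2, and positions and mitochondrial shares were compared by exact two-sided permutation tests within days (1296 arrangements for positions; 7776 for shares on all days and 36 on days 12 and 14).

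The comparisons, 32 gene lists, named-gene rule and most alternatives were fixed before the data were examined. The lists were written by hand from textbook knowledge, share some genes, and were tested with camera of limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over the lists within a comparison. Beside each list stand the members called over all genes and, where this differed, adjusted over the list alone. The rule let the text name MYC, the 8 highest and 8 lowest called genes of the averaged and UT comparisons, 3 and 3 on single days, 5 and 5 for the other comparisons, and from each list up to 4 called members with the largest change plus its most abundant member. Named genes outside lists needed an average log2 CPM of at least 1 and, in the averaged comparison, the same sign on all 5 days. Clone, locus, antisense and pseudogene names were not used, and some genes that met the rule are not reported here.

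Alternatives were DESeq2 size factors, library sizes alone, no filter, a filter of at least 1 CPM in 4 libraries, limma-voom, DESeq2 1.42.0, a fit with only the groups compared, leaving out each library or day, replicate number as a block, and a 2-fold threshold. Positions were also taken with a prior count of 0.5, the 2000 most variable genes or a line ending at UT day 20, and gene sets of the UT course also from UT day 16 or with at least 2-fold change. With a library left out, the lone library of its group was assumed to vary like the others. Removing mitochondrially encoded genes, days 12 and 14 alone, and DOX day 20 against UT day 16, also without each of its libraries, were added after seeing the data. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

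The fits were tested on simulated data. In the averaged comparison, 83.6% of genes changed 1.5-fold and 94.0% of genes changed 2-fold were recovered, with 14 unchanged genes called among 19815. The changed genes had a mean of at least 1 CPM, were drawn once, and had the same fold on every DOX day. No wider shift in composition between the arms was simulated. Recovery may therefore be lower, and false calls more frequent, in the real data. On day 14 the shares recovered were 19.4% and 62.7%, in the UT course 13.4% and 43.3%, and for the change of the difference 1.49% and 23.9%. Absence of a call on single days thus says little about changes of 2-fold or less. Where all libraries on 1 side of a comparison had 0 counts, the fold was bounded with a floor of 3 counts per library and written as at least that fold. With 1 to 3 counts on a side, a ratio with its 95% interval was given. Floors and intervals cover counting error only. Averaged folds of single genes were not bounded for days on which a group had 0 counts, and such days can inflate them. List medians were recomputed with genes at 0 counts in a group set to their bounds.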

Results

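PolyA-selected RNA was sequenced from haematopoietic progenitor cells made from H1, an established human embryonic stem cell line, while these cells were kept in culture. In 1 arm (DOX), doxycycline drove an ectopic copy of the transcription factor MYC. The other arm (UT) had no doxycycline. All libraries carry the same line name in their titles, and none had doxycycline without ectopic MYC. Effects of doxycycline itself were therefore not separated from those of MYC. UT was sampled on every other day from day 10 to day 20 and DOX from day 12 to day 20. Each of the 11 groups had 2 replicate libraries, 22 in all. The deposited values were estimated counts per gene, with totals of 24730505 to 53508561 counts per library. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

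MYC (ENSG00000136997.21, chromosome 8, 127735434 to 127741434 on the plus strand of GRCh38), a regulator of cell growth, was higher in DOX than in UT when days 12 to 20 were averaged. The difference was 1.78-fold, a log2 fold change of 0.83 (SE 0.11, adjusted p = 4.3e-06, 10 libraries per arm), and MYC was higher in DOX on all 5 days. In UT, MYC fell from 149 ± 10.3 CPM (library-scaled counts; mean ± SD, n = 2) on day 10 to 31.7 ± 4.16 on day 20, a log2 fold change of -2.24 (adjusted p = 5.5e-07). In DOX it stood at 237 ± 6.82 CPM on day 12, 174 ± 13.9 on day 14, 108 ± 34.1 on day 16, 61.1 ± 7.09 on day 18 and 39.2 ± 14.7 on day 20. The UT levels on those days were 124 ± 4.07, 73.4 ± 21.7, 53.3 ± 9.15, 39.1 ± 8.38 and 31.7 ± 4.16 CPM.

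By day, MYC in DOX against UT was called on day 12 (1.92-fold, adjusted p = 0.041), day 14 (2.37-fold, adjusted p = 0.00098) and day 16 (2.04-fold, adjusted p = 0.0027). It was not called on day 18 (1.57-fold, adjusted p = 0.0505) or day 20 (1.24-fold, adjusted p = 0.39). The narrowing from day 12 to day 20 was itself not called (log2 change -0.63, SE 0.35, adjusted p = 0.29; -1.07 and -0.29 without DOX day-20 replicate 1 and 2). The day-12 call was lost when any 1 of its 4 libraries was left out (log2 0.91 to 0.97). It was also lost with DESeq2 size factors (adjusted p = 0.0505) and with library sizes alone (adjusted p = 0.11). Library sizes alone also gave a call on day 20 and turned the sign of the narrowing. The day-16 call was lost without DOX day-16 replicate 1 (log2 0.66, adjusted p = 0.072). The day-18 call was gained with replicate number as a block (adjusted p = 0.0076), no filter (adjusted p = 0.00021), its groups alone in the fit (adjusted p = 0.040), mitochondrial genes removed (adjusted p = 0.047), library sizes alone (adjusted p = 8.5e-05) and without UT day-18 replicate 1 (log2 0.92, adjusted p = 0.039); without UT day-18 replicate 2 the log2 value was 0.44 (adjusted p = 0.29). Without DOX day-20 replicate 1 the day-20 value was -0.13 (adjusted p = 0.81). Transcripts of the endogenous and the ectopic copy shared a single row of counts and were not separated.

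**Figure D1:**
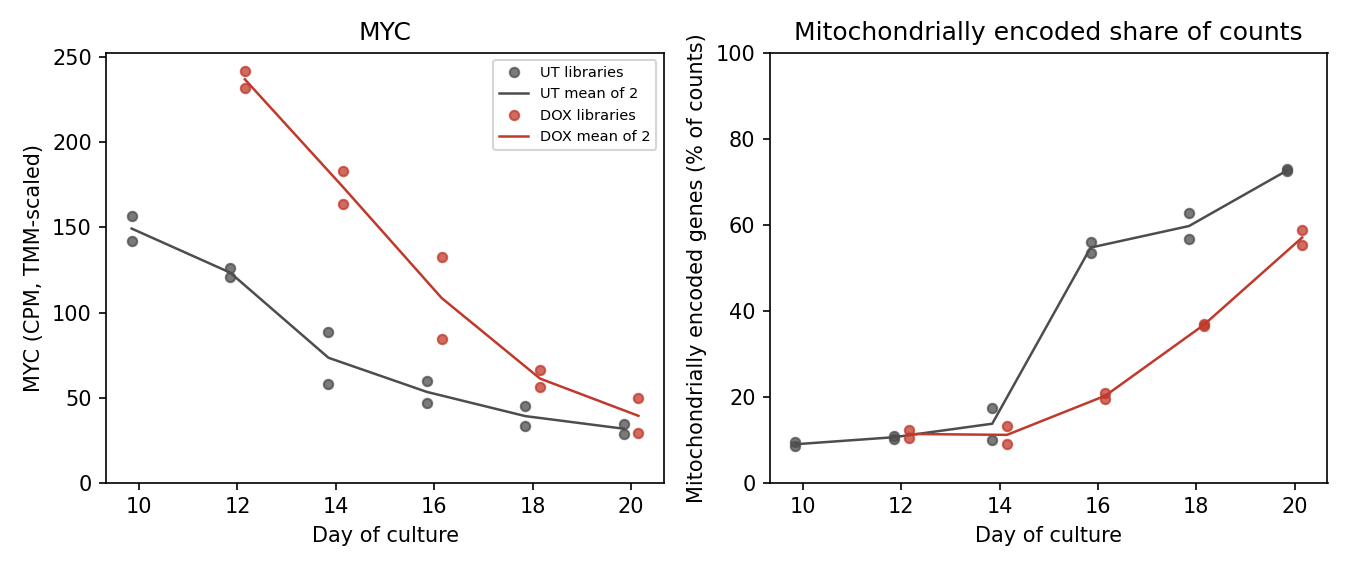
MYC in TMM-scaled CPM (left) and the mitochondrially encoded share of all counts in percent (right) against day of culture; points are single libraries (grey UT, red DOX) and lines join the means of 2. MYC in DOX runs from 237 CPM on day 12 to 39.2 on day 20, and the mitochondrial share reaches 72.7% in UT and 57.0% in DOX on day 20.

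Counts from genes of the mitochondrial genome rose through culture in both arms and differed between the arms. In UT they made up 8.92% ± 0.585 of counts (SD, n = 2) on day 10, 10.6% ± 0.441 on day 12, 13.7% ± 5.30 on day 14, 54.7% ± 1.71 on day 16, 59.7% ± 4.41 on day 18 and 72.7% ± 0.332 on day 20. In DOX they made up 11.3% ± 1.28 on day 12, 11.1% ± 2.96 on day 14, 20.2% ± 1.05 on day 16, 36.7% ± 0.263 on day 18 and 57.0% ± 2.43 on day 20. Over the 5 shared days, DOX minus UT was -15.0 percentage points (exact permutation test within days, two-sided p = 0.0036). On days 12 and 14 alone it was -0.921 points (exact permutation p = 0.78). With its 36 arrangements this test could not give a p under 0.05, so it does not show that the shares were equal. The share may mark RNA quality or the state of the cells, and no separate measure of either was used here. It is given beside some of the gene groups that moved with it.

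The first comparison asked how the transcriptome of DOX differed from that of UT over the culture. The study frames the action of ectopic MYC as a block of differentiation in acute myeloid leukaemia. Averaged over days 12 to 20, growth, nucleotide synthesis, erythroid and megakaryocyte genes were higher in DOX than in UT. Genes of granulocytes, mast cells and eosinophils and interferon-stimulated genes were lower. Among genes with an average log2 CPM of at least 1, the largest rises included C11orf87 (90.4-fold), which is named for its open reading frame, the pentraxin PTX3 (18.1-fold), the glutamate receptor gene GRM3 (11.2-fold), the argininosuccinate synthase gene ASS1 (8.59-fold) and the stanniocalcin gene STC2 (8.29-fold). The falls, under the same limit, included those of the hexokinase gene HK3 (8.28-fold lower), the defensin gene DEFA3 (6.02-fold), the membrane-type metalloproteinase gene MMP25 (5.94-fold), the myeloid receptor gene CD300LF (5.90-fold), the fatty acid receptor gene FFAR2 (5.81-fold), the NADPH oxidase gene NCF1 (5.24-fold) and the cytokine gene LIF (5.13-fold). Of these, DEFA3 and NCF1 have near-identical copies and are uncertain. C11orf87 (ENSG00000185742.7, chromosome 11, 109422120 to 109429114 on the plus strand) stood at 29.3 ± 3.11 CPM in DOX on day 12 and 58.2 ± 10.2 on day 16, against 1.73 ± 0.397 and 0.262 ± 0.307 CPM in UT (SD, n = 2). Its averaged log2 fold change was 6.50 (SE 0.20, adjusted p = 1.4e-13).

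Growth genes known as MYC targets rose together, with 27 of 29 measured members called higher, 0 lower and a median log2 fold change of 0.74 (camera adjusted p = 3.0e-18). Examples were the mitochondrial chaperone TRAP1 (1.36, SE 0.05), the amino acid transporter SLC7A5 (1.31, SE 0.09) and the chaperonin HSPD1 (1.01, SE 0.08). Purine, pyrimidine and one-carbon synthesis genes rose in 26 of 28 and fell in 1 (median 0.71, adjusted p = 3.0e-18), led by the folate enzyme ALDH1L2 (5.52, SE 0.22), the serine synthesis enzyme PSAT1 (2.08, SE 0.09) and the folate enzyme MTHFD1L (1.23, SE 0.07), with the purine enzyme PAICS at 1.06 (SE 0.07). Ribosome biogenesis genes rose in 29 of 37 and fell in 2 (median 0.41, adjusted p = 6.6e-09). WDR3 and NOB1, factors of small-subunit assembly, rose by 1.32 and 1.22, and NPM1 by 0.66. These 3 lists kept their calls with an estimated correlation (adjusted p = 0.018, 0.013 and 0.039). On days 12 and 14 alone, where the mitochondrial shares were closest, their medians were 0.55, 0.62 and 0.40 (adjusted p = 0.01, 0.0034 and 0.015 with an estimated correlation).

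Cytosolic ribosomal protein genes rose in 21 of 31 and fell in 0 (median 0.28, adjusted p = 0.00044; adjusted p = 0.26 with an estimated correlation), with RPL3 at 0.60 (SE 0.06). Glycolysis genes rose in 16 of 23 and fell in 3 (median 0.31, adjusted p = 0.00026, and 0.12 with an estimated correlation), among them the lactate transporter SLC16A1 at 1.42 and phosphofructokinase PFKM at 1.15. On day 20 their median was -0.23, with 5 members higher and 7 lower, and camera did not call the list (adjusted p = 0.21). Nuclear genes of oxidative phosphorylation rose in 20 of 24 and fell in 0 (median 0.48, adjusted p = 9.1e-06; adjusted p = 0.16 with an estimated correlation). Mitosis genes rose in 23 of 27 and fell in 1 (median 0.52, adjusted p = 4.2e-08; adjusted p = 0.063 with an estimated correlation), including the checkpoint kinase BUB1 (1.02) and the kinesin KIF20A (0.98). The topoisomerase TOP2A fell (-0.46, adjusted p = 9.9e-05), but its value was 0.068 with library sizes as the only scaling and 0.30 on days 12 and 14 alone. DNA replication genes rose in 20 of 32 and fell in 4 (median 0.22, adjusted p = 0.023; adjusted p = 0.27 with an estimated correlation), and the cell cycle transcription factor E2F2 was among those that fell (-0.82). Cholesterol and fatty acid synthesis genes rose in 16 of 24 and fell in 4 (median 0.36, adjusted p = 0.00030; adjusted p = 0.14 with an estimated correlation), with the desaturases FADS2 at 0.97 and SCD at 0.82.

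Erythroid genes rose in 22 of 27 and fell in 2 (median 1.01, or 0.94 with genes at 0 counts set to their bounds; adjusted p = 1.5e-12; adjusted p = 0.018 with an estimated correlation). Among them were the membrane skeleton gene SPTB (2.91, SE 0.13), HEMGN (2.69, SE 0.18) and, with near-identical copies and so uncertain, GYPB (2.95) and the fetal globin gene HBG2 (1.54). SLC6A9, a glycine transporter outside the list, rose 7.54-fold. Megakaryocyte and platelet genes rose in 20 of 23 and fell in 1 (median 1.08, adjusted p = 2.4e-14; adjusted p = 0.035 with an estimated correlation), with the platelet granule gene MMRN1 at 2.21 (SE 0.17), LTBP1 at 1.90 (SE 0.09), the integrin ITGB3 at 1.66 and THBS1 at 1.22. The mitochondrial share was 15.0 points lower in DOX over the same libraries. On days 12 and 14 alone, the megakaryocyte median was -0.23 with 4 members higher and 7 lower, the erythroid median was 0.13, HBG2 was at -0.10, and LTBP1, ITGB3 and THBS1 were not called.

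Neutrophil primary granule genes fell in 16 of 18 and rose in 0 (median -0.83, adjusted p = 1.0e-11; adjusted p = 0.038 with an estimated correlation), including MS4A3 (-1.58, SE 0.08), the transcription factor CEBPE (-1.42, SE 0.10) and myeloperoxidase MPO (-0.82, SE 0.07). The eosinophil ribonucleases RNASE3 (-1.65) and RNASE2 (-1.44) are members of this list and of the mast cell, basophil and eosinophil list. Later granule and mature neutrophil genes fell in 16 of 22 and rose in 1 (median -1.67, adjusted p = 6.0e-09; adjusted p = 0.023 with an estimated correlation), with the chemokine receptor CXCR1 at -6.08 (SE 0.57; 6 counts in all DOX libraries against 225 in UT, so near the floor), lactoferrin LTF at -3.23 (SE 0.23) and S100A8 at -2.02 (SE 0.10). Mast cell, basophil and eosinophil genes fell in 19 of 22 and rose in 1 (median -1.46, adjusted p = 1.3e-16; adjusted p = 0.018 with an estimated correlation). Their named members were the IgE receptor subunit MS4A2 (-2.32), the eotaxin receptor CCR3 (-2.27), SIGLEC8 (-2.15), histidine decarboxylase HDC (-1.94) and the eosinophil granule protein PRG2 (-1.85). KIT, a list member that also marks progenitors, rose by 1.67. Over the same libraries the mitochondrial share was 15.0 points lower in DOX.

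Monocyte and macrophage genes fell in 25 of 30 and rose in 1 (median -0.81, adjusted p = 3.0e-10; adjusted p = 0.063 with an estimated correlation), with SIGLEC1 at -2.33 and VCAN at -1.96. MHC class II and dendritic cell genes fell in 18 of 21 and rose in 1 (median -0.88, adjusted p = 5.4e-06; adjusted p = 0.090 with an estimated correlation), with CD207 at -1.88 (133 and 263 counts in DOX and UT; -2.83 to -1.50 without 1 library) and the invariant chain CD74 at -0.82. Lymphoid genes fell in 10 of 18 and rose in 1 (median -1.15, or -1.04 at bounds; adjusted p = 0.00093; adjusted p = 0.022 with an estimated correlation), IGLL1 being at -2.49. Myeloid transcription factors fell in 25 of 33 and rose in 3 (median -0.61, adjusted p = 1.4e-08; adjusted p = 0.038 with an estimated correlation), with KLF2 at -2.24, RUNX2 at -1.40 and CEBPB at -1.23. Interferon-stimulated genes fell in 16 of 25 and rose in 0 (median -0.81, adjusted p = 6.0e-05, and 0.026 with an estimated correlation). Camera did not call this list on day 18 (median -0.30, 1 higher and 6 lower, adjusted p = 0.11) or day 20 (-0.25, 2 higher and 3 lower, adjusted p = 0.20). The values of IFI44 (-2.96) and OASL (-2.09) rested on few counts, and their calls were lost without UT day-18 replicate 2 (IFI44 -1.62) and UT day-20 replicate 1 (OASL -0.51). Inflammatory cytokine and chemokine genes fell in 13 of 22 and rose in 3 (median -0.54, adjusted p = 0.0098, and 0.26 with an estimated correlation), with CCL20 at -2.05 and CCL2 at -1.50. This fall did not hold on day 20, when 7 members were higher and 0 lower in DOX (median 0.22, camera adjusted p = 0.070). Lysosome genes fell in 21 of 28 and rose in 5 (median -0.32, adjusted p = 0.00011; adjusted p = 0.15 with an estimated correlation). With library sizes alone the lysosome median was 0.21, the list was not called (adjusted p = 0.23), and its member CTSZ went from -0.27 to 0.27; CTSZ was not called without day 14 (-0.17). All 13 mitochondrially encoded mRNAs fell (median -0.97, adjusted p = 1.8e-08; adjusted p = 0.16 with an estimated correlation), with MT-CO1 at -1.47.

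The other 10 lists were not called. Stem and progenitor genes were higher in 7 and lower in 12 of 30 (median -0.15, adjusted p = 0.73); KIT (1.67), FLT3 (1.70) and MLLT3 (1.54) rose and AVP fell (-2.12). HOXA and HOXB genes were higher in 2 and lower in 4 of 13 (median -0.15, adjusted p = 0.70), with HOXB7 at -1.08. CDK inhibitors and p53 targets were higher in 13 and lower in 3 of 22 (median 0.31, adjusted p = 0.18), and the neighbouring genes CDKN2A (1.36) and CDKN2B (-1.60) went opposite ways. Endothelial genes were higher in 8 and lower in 2 of 21 (median 0.19, adjusted p = 0.12), with APLNR at 2.04 and PECAM1 at 0.67. Fibroblast genes were higher in 2 and lower in 3 of 21 (median -0.21, adjusted p = 0.73). Pluripotency genes were higher in 5 and lower in 2 of 15 (median 0.41, or 0.03 at bounds; adjusted p = 0.19), among them LIN28A (2.53) and ZFP42 (1.96). Chromatin regulators were higher in 12 and lower in 4 of 26 (median 0.13, adjusted p = 0.24), including TET1 at 1.34. MYC network partners were higher in 4 and lower in 3 of 12 (median -0.09, adjusted p = 0.85), with MXI1 at 0.94 and MYCL at -0.81. BCL2 family genes were higher in 6 and lower in 4 of 14 (median 0.07, adjusted p = 0.88), BCL2A1 being at -2.04. Immediate early and stress genes were higher in 5 and lower in 11 of 22 (median -0.26, adjusted p = 0.24), while CHAC1 (3.01) and asparagine synthetase ASNS (2.32), targets of the amino acid response, rose.

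In this averaged comparison, 10636 of 20115 genes were called at an adjusted p under 0.05, 6002 higher and 4634 lower in DOX, and 2970 of them differed by at least 2-fold (1415 higher, 1555 lower). Adjusted over the list alone, counts of members differed from those above in 9 lists: cytosolic ribosomal proteins 21 higher and 1 lower, CDK inhibitors 13 and 4, stem and progenitor genes 7 and 13, lymphoid genes 1 and 12, interferon-stimulated genes 1 and 16, lysosome 6 and 21, cholesterol and fatty acid synthesis 20 and 4, chromatin regulators 12 and 5, and BCL2 family 7 and 4. Of the 85 genes named in this comparison, 76 had the same sign on all 5 days. The other 9 were TOP2A, FLT3, HBG2, MMRN1, LTBP1, ITGB3, THBS1, PECAM1 and MYCL. Genes outside lists were named only if their sign was the same on all 5 days, so the count of 76 is partly fixed by choice. With library sizes as the only scaling, the median log2 fold change of all genes shifted by 0.53 and the split was 11582 higher and 1610 lower, so directions are relative to the median gene. On days 12 and 14 alone 5039 genes were called (2857 higher, 2182 lower), and 14 named genes lost their calls. In TOP2A and HBG2 the sign reversed, and in LTBP1 (0.33), ITGB3 (0.32), THBS1 (0.17), E2F2 (-0.18), FLT3 (0.57), HOXB7 (-0.54), APLNR (0.37), PECAM1 (0.18), MT-CO1 (-0.39) and MYCL (-0.16) the log2 fold change shrank. CD207 (-1.48, against -1.88 over all days) and OASL (-2.37, against -2.09) stayed about as large.

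Single days were compared to see when these differences appeared. On day 12, growth (7 members called higher, median 0.42), ribosome biogenesis (8, 0.47), nucleotide synthesis (8, 0.44) and mitosis genes (7, 0.44) were already higher in DOX, with 0 members lower in these 4 lists. Adjusted over the list alone, the counts were 18, 22, 18 and 14. Mast cell, basophil and eosinophil genes (12 lower, median -1.29), monocyte genes (11, -1.04), interferon-stimulated genes (10, -0.96), primary granule genes (10, -0.78) and inflammatory genes (9, -0.94) were lower with 0 members higher; adjusted over the list alone, 14, 23, 17, 14 and 16 were lower. These 9 lists were called with either correlation (largest adjusted p = 0.0091 with an estimated correlation). Megakaryocyte genes were lower in DOX on this day, with 4 of 23 called lower, 9 adjusted over the list alone, 0 higher and a median of -0.45 (adjusted p = 3.6e-11; adjusted p = 0.031 with an estimated correlation). Of single genes, C11orf87 rose 16.8-fold, PTX3 13.0-fold and the metallothionein MT1X 4.79-fold, while CCL20 fell 6.82-fold and XAF1, an interferon-stimulated gene, 4.98-fold. Without 1 library, log2 values ran from 1.75 to 2.96 in MT1X and from -3.26 to -2.07 in CCL20. DEFA3 had 2 counts in DOX and 33 in UT, a ratio of 20.7 (95% counting interval 5.30 to 178; log2 -6.58 to -3.34 without 1 library). The mitochondrial shares were 11.3% and 10.6%.

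The day-12 test called 625 genes, 170 higher and 455 lower in DOX. Without UT replicate 1 or 2 it called 75 or 234, and without DOX replicate 1 or 2 it called 144 or 69. MT1X, CCL20, XAF1 and DEFA3 lost their calls without 1 or more of these libraries. The count was 4742 when the fit held these 4 libraries alone. It was 63 higher and 409 lower with library sizes alone, and 643 and 888 with limma-voom.

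On day 14, with mitochondrial shares of 11.1% in DOX and 13.7% in UT, the mast cell list reached its lowest median (-2.10, 18 of 22 lower and 1 higher; adjusted p = 2.2e-19; adjusted p = 0.012 with an estimated correlation). The cytokine genes OSM and LIF were 13.8-fold and 12.9-fold lower in DOX, ASNS was 7.63-fold, C11orf87 47.7-fold and PTX3 16.4-fold higher, and EIF3CL, which has a near-identical copy and is uncertain, was 21.3-fold lower. Chromatin regulators were higher in 13 and lower in 1 of 26 (median 0.45, adjusted p = 0.00013; adjusted p = 0.032 with an estimated correlation; 17 and 1 adjusted over the list alone). Megakaryocyte genes were higher in 7 and lower in 5 (median 0.16, adjusted p = 0.78). The test called 5422 genes, 3070 higher and 2352 lower, and 2859 without DOX day-14 replicate 2.

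From day 16 on, megakaryocyte and erythroid genes stood higher in DOX. The megakaryocyte median was 1.60 on day 16, 2.30 on day 18 and 1.94 on day 20 (18, 21 and 21 of 23 called higher), and the erythroid median 1.36, 2.55 and 1.59 (17, 21 and 17 of 27 called higher; medians 1.31, 1.99 and 1.59 at bounds). Adjusted p with an estimated correlation was 0.060, 0.010 and 0.017 for the megakaryocyte list and 0.060, 0.010 and 0.017 for the erythroid list. On the same days the mitochondrial share was 20.2%, 36.7% and 57.0% in DOX against 54.7%, 59.7% and 72.7% in UT. Growth genes stayed higher (medians 0.93, 0.70 and 0.77; adjusted p = 0.0498, 0.096 and 0.017 with an estimated correlation). Later neutrophil granule genes stayed lower (-1.90, -1.36 and -1.90; adjusted p = 0.063, 0.096 and 0.017 with an estimated correlation). On day 16, C11orf87 was 212-fold and STC2 28.5-fold higher, and the read-through gene HNRNPUL2-BSCL2, which overlaps its parent genes and is uncertain, was at least 366.5-fold higher. FN1, COL3A1 and COL1A1, genes of fibroblast matrix, were 39.6-fold, 26.3-fold and 20.4-fold lower on day 16, but UT day-16 replicate 2 held 5789, 7402 and 3283 of their counts against 34, 27 and 40 in replicate 1. Without that library their log2 values were 0.96, 2.23 and 0.88 (adjusted p = 0.44, 0.027 and 0.31), and limma-voom did not call them. On day 18, HK3 was 9.50-fold and FFAR2 9.43-fold lower, and NBPF19, of a family of near-identical copies and uncertain, 10.6-fold lower.

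**Figure D2:**
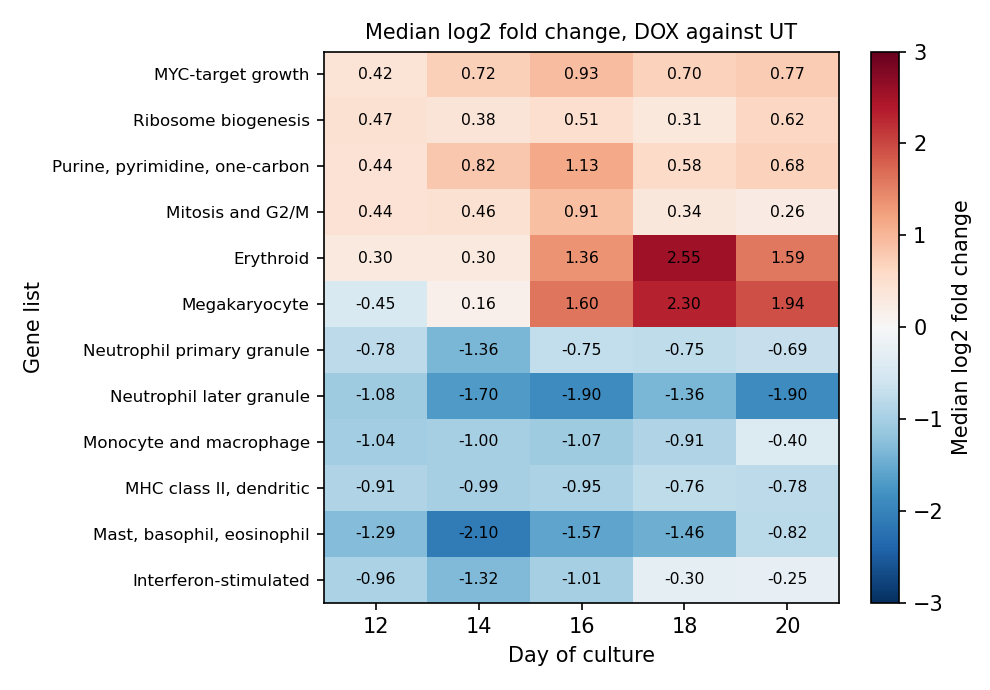
Median log2 fold change of 12 gene lists (rows) in DOX against UT on each day of culture (columns), coloured from blue (lower in DOX) to red (higher) and printed in each cell. Megakaryocyte genes run from -0.45 on day 12 to 2.30 on day 18; with library sizes alone, which raised the median of all genes by 0.93, 0.91 and 0.91 on days 16, 18 and 20, medians were above 0 for primary granule genes on those 3 days, for MHC class II and interferon genes on days 18 and 20, and for monocyte and mast cell genes on day 20.

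The tests called 8028 genes on day 16 (4273 higher, 3755 lower), 7202 on day 18 (3978 and 3224) and 5585 on day 20 (3195 and 2390). With library sizes alone the splits were 10275 and 1004, 10801 and 645, and 10657 and 437. The day-20 count was 3592 without DOX day-20 replicate 1, and 2035 with its 4 libraries alone in the fit. Comparisons on different days shared no library, but all came from 1 fit, with 1 estimate of spread per gene for every day. Genes with a small spread are called more readily on any day, which alone can raise overlap. Higher on both day 14 and day 20 were 1074 genes (487.6 for independent lists), and lower on both 901 (279.5). Opposite calls, which a small spread would also raise, numbered 205 first higher (364.8) and 189 first lower (373.6). Of the 170 genes higher on day 12, 130 were higher and 0 lower on day 20 (27 and 20.2 for independent lists). Of the 455 genes lower on day 12, 245 were lower on day 20 (54.06 for independent lists) but 65 were higher (72.27).

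The course without ectopic MYC was described by UT day 20 against UT day 10. Genes of eosinophils rose from low to high levels. PRG2, the major basic protein, went from 6.29 ± 0.873 to 15990 ± 2290 CPM (SD, n = 2), eosinophil peroxidase EPX rose 1796-fold, PRG3 969-fold and the interleukin-5 receptor IL5RA 1127-fold. Neutrophil genes rose too, to day-20 means of 6.23 CPM in ELANE, 8.44 in CEACAM8, 9.61 in ARG1, 26.3 in DEFA4 and 321 in S100A8. Mast cell, basophil and eosinophil genes rose in 19 of 22 and fell in 1 (median 5.30, or 5.17 at bounds; adjusted p = 1.6e-22; adjusted p = 0.019 with an estimated correlation; 20 and 1 adjusted over the list alone). Primary granule genes rose in 15 of 18 and fell in 0 (median 5.33, adjusted p = 6.9e-17; adjusted p = 0.021 with an estimated correlation), with SERPINB10, CEBPE and neutrophil elastase ELANE (8 counts on day 10) up 129-fold, 103-fold and 88.3-fold. Later neutrophil genes rose in 19 of 22 and fell in 1 (median 7.05, or 6.08 at bounds; adjusted p = 2.4e-10; adjusted p = 0.021 with an estimated correlation), S100A8 by 127-fold. Arginase ARG1 and CEACAM8 had 0 counts on day 10 and were at least 187-fold and 164-fold higher on day 20. DEFA4 had 1 count on day 10 and 569 on day 20, a ratio of 3101 (95% counting interval 554 to 122686), and DEFA3, uncertain for its near-identical copy, a ratio of 2118 (723 to 10285). HK3 rose by 10.73 on the log2 scale, the eotaxin gene CCL24 (6 counts on day 10) 1663-fold, ITGAX 123-fold, FCGR3A (7 counts) 90.7-fold, and FABP4, with 1 count on day 10, by a ratio of 1875 (334 to 74257). UTP14C, which overlaps other genes and is uncertain, had 0 counts on day 10 and was at least 731-fold higher. The mitochondrial share went from 8.92% to 72.7% over the same days, and all 13 mitochondrially encoded mRNAs rose (median 5.18, adjusted p = 4.6e-20; adjusted p = 0.055 with an estimated correlation), MT-ND1 by 49.7-fold.

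Megakaryocyte genes fell in 19 of 23 and rose in 1 over the UT course (median -4.23, adjusted p = 3.0e-15; adjusted p = 0.036 with an estimated correlation), MMRN1 by 200-fold, ITGB3 by 97.4-fold and THBS1 by 76.5-fold. Erythroid genes fell in 21 of 27 and rose in 1 (median -2.91, or -2.88 at bounds; adjusted p = 1.1e-09; adjusted p = 0.027 with an estimated correlation), with RHAG 164-fold and HBG2 46.7-fold lower; GYPB had 2 counts on day 20, a ratio of 479 (133 to 3958). Endothelial genes fell in 14 of 21 and rose in 1 (median -2.30, or -2.14 at bounds; adjusted p = 7.1e-06; adjusted p = 0.021 with an estimated correlation; 15 and 1 adjusted over the list alone): TEK (5 counts on day 20) was 230-fold and KDR 66.8-fold lower, and CDH5 had 2 counts on day 20, a ratio of 144 (39.7 to 1188). Stem and progenitor genes as a list were not called (median -0.43, 15 of 30 down and 10 up; adjusted p = 0.21). Of them KIT, CD34 and ANGPT1 fell 20.7-fold, 21.0-fold and 23.8-fold, and HOPX, with 1 count on day 20, by a ratio of 49.7 (8.85 to 1971). The pluripotency gene LIN28A, with 2 counts on day 20, fell by a ratio of 1768 (489 to 14597). MYCN fell 53.9-fold. Growth genes fell in 23 of 29 and rose in 2 (median -1.21, adjusted p = 2.0e-07; adjusted p = 0.073 with an estimated correlation; 24 and 2 adjusted over the list alone), with SLC7A5, HSPE1 and TRAP1 6.45-fold, 6.01-fold and 5.30-fold lower. The glycolytic gene PFKM fell 8.71-fold and BUB1 6.65-fold, whereas KLF2 rose 116-fold, RUNX2 111-fold and GADD45B by 4.39 on the log2 scale. TOP2A rose 3.88-fold, but its log2 value was -0.24 with library sizes alone.

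Other lists that camera called over the UT course lost their calls with an estimated correlation. Higher on day 20 were monocyte genes (median 2.29, 18 of 30 up and 4 down; adjusted p = 0.20 with an estimated correlation) and MHC class II genes (2.25, 17 of 21 up and 0 down; adjusted p = 0.15 with an estimated correlation). Lower were nucleotide synthesis genes (-1.44, 24 of 28 down and 2 up; adjusted p = 0.073 with an estimated correlation), mitosis genes (-1.26, 22 of 27 down and 3 up; adjusted p = 0.17 with an estimated correlation) and nuclear oxidative phosphorylation genes (-1.43, 19 of 24 down and 3 up; adjusted p = 0.20 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 17 and lower in 4 of 31 (0.37; adjusted p = 0.28 with an estimated correlation), but their median was -1.81 with library sizes alone.

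In the UT course 12525 genes were called, 5653 higher and 6872 lower on day 20, and 14638 differed on any UT day from day 10 to day 20. In DOX, 12034 differed on any day from day 12 to day 20. DOX had no day-10 libraries, so these counts do not show which arm changed more. With library sizes alone the median of all genes shifted by -2.18 and the UT split was 1454 higher and 14451 lower.

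DOX day 20 against UT day 10 gave the course with ectopic MYC, from the only day-10 libraries. PRG2 rose 1189-fold to 7497 ± 433 CPM, FABP4 had 1 count in UT on day 10 against 658, a ratio of 1877 (95% counting interval 336 to 74242), and UTP14C was at least 209-fold higher. Mast cell, basophil and eosinophil genes rose in 20 of 22 (median 5.27, or 4.67 at bounds; adjusted p = 8.6e-24; adjusted p = 0.015 with an estimated correlation). Megakaryocyte genes fell in 16 of 23 and rose in 3 (median -1.86, adjusted p = 7.4e-07; adjusted p = 0.12 with an estimated correlation), and erythroid genes fell in 20 of 27 and rose in 3 (median -1.52, adjusted p = 8.5e-06; adjusted p = 0.10 with an estimated correlation). MYC fell by 1.93 on the log2 scale (SE 0.25). The mitochondrial share was 57.0% against 8.92%. In all, 11617 genes were called, 5523 higher and 6094 lower, or 1896 and 11948 with library sizes alone, which shifted the median of all genes by -1.26.

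Whether DOX libraries lay at an earlier point of the course that UT libraries took was asked with a line through gene expression from the UT day-10 mean (0) to the UT day-18 mean (1). UT libraries stood at 0.112 ± 0.0115 (SD, n = 2) on day 12, 0.423 ± 0.0160 on day 14, 0.743 ± 0.00520 on day 16 and 0.963 ± 0.0153 on day 20. DOX libraries stood at 0.0606 ± 0.00671 on day 12, 0.172 ± 0.0262 on day 14, 0.349 ± 0.000515 on day 16, 0.571 ± 0.0255 on day 18 and 0.739 ± 0.0510 on day 20. Over days 12, 14, 16 and 20, DOX minus UT was -0.230 (exact permutation test within days, two-sided p = 0.0015, the smallest that the 1296 arrangements allow); day 18 was left out because its UT libraries set the line.

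**Figure D3:**
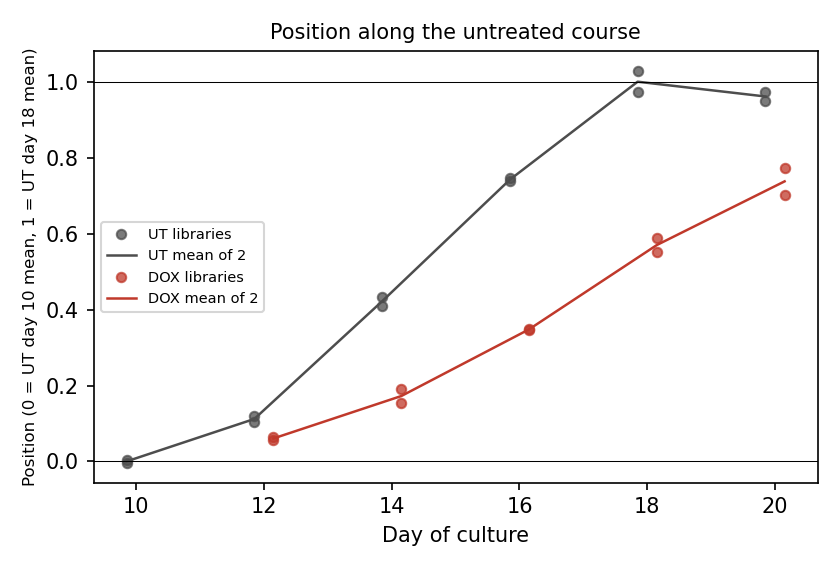
Position of each library on the line from the UT day-10 mean (0) to the UT day-18 mean (1), without unit, against day of culture; points are libraries (grey UT, red DOX) and lines join the means of 2. DOX means lie below UT means of the same day, at 0.739 against 0.963 on day 20.

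Genes that changed along the UT course were then followed in DOX against UT on day 20, libraries that had no part in choosing them. The 5785 genes that rose from UT day 10 to day 18 had a median log2 fold change of -0.35 in DOX on day 20, with 1562 called lower and 411 higher (camera p = 1.8e-15; p = 0.00065 with an estimated correlation). The 6753 genes that fell had a median of 0.33, with 1938 called higher and 330 lower (camera p = 7.3e-12; p = 0.0041 with an estimated correlation). Without 1 library these medians ran from -0.48 to -0.27 and from 0.22 to 0.44. The sets were not tested with library sizes alone, which shifted the median of all genes by 0.91 on day 20 and called 437 genes lower. Both medians and counts are thus relative to the median gene. Since the sets together held most genes tested, medians on opposite sides of 0 may partly follow from the scaling. The mitochondrial share, which rose along this course, was 57.0% in DOX and 72.7% in UT on day 20.

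The last comparison tested whether the DOX against UT difference itself moved from day 12 to day 20. In platelet genes the difference moved upward, by 4.20 in VWF (SE 0.76), 4.05 in GP1BA (SE 0.45), 3.89 in PPBP (SE 0.30) and 3.81 in PF4 (SE 0.33) on the log2 scale, and 20 of 23 megakaryocyte genes moved up and 1 down (median 2.60, adjusted p = 1.8e-46; adjusted p = 0.0026 with an estimated correlation). In erythroid genes 11 of 27 moved up and 0 down (median 1.43, adjusted p = 3.9e-09; adjusted p = 0.042 with an estimated correlation; 13 and 0 adjusted over the list alone), with RHD at 3.60, SPTB at 3.42, RHAG at 3.24 and HBE1 at 3.13. In inflammatory genes 9 of 22 moved up and 0 down (median 1.55, adjusted p = 1.7e-10; adjusted p = 0.042 with an estimated correlation; 14 and 1 adjusted over the list alone), among them the neutrophil chemokines CXCL8 (3.24) and CXCL2 (3.18). In CDK inhibitors and p53 targets 6 of 22 moved up and 0 down (median 0.49, adjusted p = 0.00015; adjusted p = 0.012 with an estimated correlation; 8 and 0 adjusted over the list alone), with FDXR at 2.01 (SE 0.21) and CDKN1A at 1.92 (SE 0.24). APLNR (3.96), MYCN (3.19) and MEIS1 (2.19) moved up as well. The mitochondrial share was 11.3% in DOX and 10.6% in UT on day 12 and 57.0% and 72.7% on day 20, and all 13 mitochondrially encoded mRNAs moved down (median -1.47, adjusted p = 7.0e-14; adjusted p = 0.13 with an estimated correlation). In all, 1802 genes were called, 1131 upward and 671 downward. With library sizes alone, which shifted the median of all genes by 0.98, the split was 9440 and 100; without UT day-12 replicate 1 or 2, DOX day-12 replicate 1 or 2, or DOX day-20 replicate 1, the count was 983, 987, 1010, 940 or 1124.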

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

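The comparison of DOX day 20 with UT day 16 in this part was chosen after the result was seen. The results here were singled out because the DOX against UT difference on day 20 differed from that on day 12, by a test of the difference itself. It called 1802 genes. Platelet genes moved up, VWF by 4.20, GP1BA by 4.05, PPBP by 3.89 and PF4 by 3.81 on the log2 scale, as did the erythroid genes RHD (3.60), SPTB (3.42), RHAG (3.24) and HBE1 (3.13). The chemokine genes CXCL8 (3.24) and CXCL2 (3.18), the p53 targets FDXR (2.01) and CDKN1A (1.92), and APLNR (3.96), MYCN (3.19) and MEIS1 (2.19) moved up too. Genes outside the lists changed more than these. With only the 4 groups compared in the fit, RHD kept its value (3.59) but not its call. Without DOX day-20 replicate 1 its value was 2.58, and without replicate 2 it was 4.16.

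Of the lists, megakaryocyte (median change 2.60), inflammatory (1.55), erythroid (1.43) and CDK inhibitor genes (0.49) moved up with either correlation. The 9 others were called with the preset correlation only. Growth genes moved by 0.41 (adjusted p = 0.40 with an estimated correlation), nucleotide synthesis genes by 0.36 (0.43), endothelial genes by 0.25 (0.060), immediate early genes by 0.32 (0.43) and mitochondrially encoded mRNAs by -1.47 (0.13). Glycolysis genes moved by -0.52 (0.15), monocyte genes by 0.62 (0.61), fibroblast genes by 1.22 (0.66) and interferon-stimulated genes by 0.83 (0.13), and library sizes alone ended these 4 calls. Replicate number as a block ended the fibroblast call as well (camera adjusted p = 0.059).

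Megakaryocyte and erythroid genes were higher in DOX than in UT on day 20 while the mitochondrial share was lower. Between groups with like shares, DOX day 20 (57.0%) and UT day 16 (54.7%), the megakaryocyte median was -0.14 (adjusted p = 0.13) and the erythroid median -0.10 (adjusted p = 0.45). Of 23 megakaryocyte members, 1 was called higher and 3 lower in DOX, and of 27 erythroid members 6 were higher and 3 lower. Of all 20115 genes, 1413 were called. The erythroid median near 0 thus hides members that differed in both directions. A state of the RNA or of the cells marked by that share would give medians near 0. So would a slower course along the UT path, since these groups also lay at like positions on the UT line (0.739 and 0.743). This comparison therefore cannot tell these explanations apart. Without 1 of these 4 libraries the megakaryocyte median was -0.43 to -0.09, and it was called lower without DOX day-20 replicate 1 (adjusted p = 0.0021; adjusted p = 0.40 with an estimated correlation). A course of DOX cultures that lagged along the path of UT cultures needs megakaryocyte genes, lower in DOX on day 12, to rise first in UT. From UT day 10 to day 12 their median rose by 0.77 (camera adjusted p = 0.0076 with an estimated correlation). Both results use the same UT day-12 libraries, and high megakaryocyte values there would give both, so the rise is no independent test. Both explanations may hold and were not separated, since share and position moved together through culture. A change of lineage caused by MYC or by doxycycline stays open as well.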

How the results depend on the processing

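Removing mitochondrially encoded genes, days 12 and 14 alone, and DOX day 20 against UT day 16 were chosen after the results were seen. Where a count of called genes moved by more than 1.5 times, the cause was not tested, except that a stricter threshold lowers a count by construction. A change of at least 2-fold left 2970 genes averaged over days, 255 on day 12, 2061 on day 14, 4263 on day 16, 3855 on day 18 and 2733 on day 20. Days 12 and 14 alone gave 5039. With library sizes alone, day 18 gave 11446, day 20 gave 11094 and the change of the difference 9540. With only the groups compared in the fit, day 12 gave 4742, day 18 gave 4783, day 20 gave 2035 and the change of the difference 1078. Day 12 gave 941 without a filter, 949 with replicate number as a block, 1531 with limma-voom and 1408 with DESeq2, which gave 2758 for the change of the difference.

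Leaving out 1 library gave 69 to 234 genes on day 12, 2859 (without DOX day-14 replicate 2) to 4246 on day 14, 3592 (without DOX day-20 replicate 1) to 5529 on day 20 and 940 to 2456 for the change of the difference. The averaged comparison gave 9952 to 10806 without 1 library. With an estimated correlation, 11 of 22 lists averaged over days kept a call, 7 of 19 on day 20, 6 of 23 in the UT course and 4 of 13 for the change of the difference. The position of DOX against UT kept its sign under each alternative run (-0.25 to -0.20); its p was the smallest possible in all and so measures no stability. Replicate numbers gave little sign of pairing: correlations between groups were -0.0155 to 0.195, 5 of 55 above 0.1, and a block on them changed some calls, as given here.

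Of 2104 comparisons of named genes without 1 library, 2080 kept direction and call, 19 lost and 1 gained a call, and 4 reversed. Of 1980 under other settings, 1946 kept both, 22 lost and 6 gained a call, and 6 reversed. Most of these genes were named for large called changes, so neither count speaks for the other genes. The reversals averaged over days were TOP2A (0.068 with library sizes alone, 0.30 on days 12 and 14), HBG2 (-0.10 on days 12 and 14) and CTSZ (0.27 with library sizes alone). With library sizes alone TOP2A in the UT course was -0.24 and the change of the MYC difference 0.37. Without 1 library, FN1 on day 16 ran from -6.30 to 0.96, COL3A1 from -5.71 to 2.23 and COL1A1 from -5.33 to 0.88, the upper ends without UT day-16 replicate 2, which held most of their UT counts. MYC on day 20 ran from -0.13 to 0.65.

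MYC on day 12 was not called with DESeq2 size factors (0.90, adjusted p = 0.0505) or library sizes alone (0.88, adjusted p = 0.11), or without any 1 library (0.91 to 0.97). MYC on day 16 was not called without DOX day-16 replicate 1 (0.66). MYC on day 18 was called with library sizes alone (1.58), no filter (0.68), a block (0.66), mitochondrial genes removed (0.66), only its groups (0.62) and without UT day-18 replicate 1 (0.92), and on day 20 with library sizes alone (1.25). CXCR1, CD207, IFI44 and OASL gave no value with the stricter filter, nor MT-CO1 and MT-ND1 with mitochondrial genes removed.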

Other observations

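Tests chosen after the result was seen in this part were DOX day 20 against UT day 16, the growth lists on days 12 and 14 and C11orf87 against UT levels. In DOX day 20 against UT day 16, groups with like mitochondrial shares, MHC class II genes were lower in DOX in 15 of 21 and higher in 1 (median -1.71, adjusted p = 0.018 with an estimated correlation). Interferon-stimulated genes were lower in 7 of 25 and higher in 0 (-0.86, adjusted p = 0.018 with an estimated correlation), and nucleotide synthesis genes higher in 11 of 28 and lower in 0 (0.45, adjusted p = 0.018 with an estimated correlation). Also called with it were ribosome biogenesis (0.38, 9 of 37 higher and 0 lower, adjusted p = 0.042) and lymphoid genes (-0.65, or -0.42 at bounds; 0 of 18 higher and 3 lower, adjusted p = 0.020). Primary granule (-0.46), later neutrophil (-1.03), mast cell, basophil and eosinophil (-0.55) and monocyte genes (-0.89) were not called with an estimated correlation (adjusted p = 0.23, 0.095, 0.23 and 0.23). Their members called lower were 4, 6, 8 and 10, and higher 0, 0, 1 and 0. Fibroblast genes were lower in 11 of 21 and higher in 0 (-2.45, adjusted p = 0.33 with an estimated correlation). UT day-16 replicate 2 stood apart in them, with FN1 at 231 CPM against 1.51 in replicate 1. Without that library the medians were 0.56 for fibroblast, -1.43 for MHC class II (adjusted p = 0.027 with an estimated correlation), -0.69 for interferon-stimulated (adjusted p = 0.060 with an estimated correlation) and 0.35 for nucleotide synthesis genes (adjusted p = 0.070 with an estimated correlation). Without DOX day-20 replicate 2, MHC class II (-1.73), interferon-stimulated (-0.88) and lymphoid genes (-1.33) lost their calls with an estimated correlation (adjusted p = 0.081 for each); the lymphoid median was -1.20 without DOX day-20 replicate 1. This comparison called 1413 genes, 583 higher and 830 lower in DOX, but 642 or 804 without UT day-16 replicate 1 or 2 and 885 or 1183 without DOX day-20 replicate 1 or 2.

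The averaged DOX against UT difference of 10636 genes was set against other groupings of the same libraries within days. Of 50 groupings out of 3888 possible, 1, the real one, gave as many. The highest other gave 6739, with 3 days grouped as labelled or mirrored. With 50 groupings the share can be no smaller than 1 of 50. If replicates were not separate cultures, libraries cannot be freely exchanged, and mixing the arms widens the spread within groups. The count was thus larger than in the other groupings drawn, but chance assignment of libraries to arms is not excluded as its source.

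Growth, ribosome biogenesis and nucleotide synthesis genes were higher in DOX. On days 12 and 14, where the mitochondrial shares were closest, the lowest of the 3 medians was 0.40 and all 3 lists were called with an estimated correlation. This argues against a state of the RNA marked by these shares as their whole cause. DOX day 12 against UT day 10 had a lowest median of 0.057, and ribosome biogenesis alone was called (adjusted p = 0.037; adjusted p = 0.41 with an estimated correlation). A slower course of DOX cultures along the UT path and an effect of MYC or of doxycycline on these genes cannot be told apart by that test. The reason is that the 3 medians fell by 0.35, 0.33 and 0.45 from UT day 10 to day 12 (with an estimated correlation only nucleotide synthesis was called, adjusted p = 0.011). An effect of MYC or of doxycycline may also add to a slower course or to the state of the RNA. At like positions on the UT line (DOX day 20 at 0.739, UT day 16 at 0.743) the medians of growth, ribosome biogenesis and nucleotide synthesis genes were 0.38, 0.38 and 0.45, and 0.35 at lowest without 1 of these libraries, which goes against a slower course as their whole cause. With an estimated correlation growth genes were not called there (adjusted p = 0.12), and ribosome biogenesis lost its call without any 1 library and nucleotide synthesis without UT day-16 replicate 2, so it is not excluded.

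C11orf87 was raised in DOX from day 12. Its mean there was 16.9 times the highest mean of any UT day, which argues against a slower course along the UT path. Its 9 measured neighbours within 1 Mb had a median log2 fold change of 0.93, 2 called higher and 1 lower, between the bounds of at least 1 and below 0.5 set for an effect on its surroundings. For 1 of the 9 the SE was 1600. On day 12, when C11orf87 was at 4.07, no neighbour was called (lowest adjusted p = 0.41) and their values ran from -1.98 to 1.32. Whether such an effect may contribute cannot be told apart from a direct effect of MYC or of doxycycline, since the median lay between those bounds and the neighbours went both ways.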
